A study of Caenorhabditis elegans with 2 samples.

How the data were processed

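Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an anti-GFP antibody on whole Caenorhabditis elegans young adults, aged 65 hours after synchronisation by starvation at the L1 larval stage. The worms carried a CRISPR insertion that adds TY1, eGFP and 3xFLAG tags to HINF-1, the product of hinf-1 (F39B2.1). Per the labels, chromatin was sonicated and the size range was 200 to 800 bp. There was 1 group with 2 biological replicates, numbered as the labels number them, and no second condition. A control experiment is named in the labels and was not used here.

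The authors deposited 8 peak lists on build ce11, which were the starting point. Per the file headers, each list was derived from the filtered alignments of 1 replicate or of both, together with another input. The peak caller and its version are not given in the sources used here. Column 7 of each list holds the signal value that the authors' peak caller gave to the peak, with no stated scaling, so it was used only to describe, rank and filter peaks within its own list. The deposited ranked lists also give the −log10 of the global irreproducible discovery rate (IDR), a measure of how well a peak's rank repeats between 2 peak sets. All peaks of the thresholded lists had a value of 2 or more, that is a global IDR of 0.01 or less, when tested on the files. The 4 ranked lists hold 32 further columns with values of peak sets that carry no sample name, and these were not used. The thresholded lists have another input whose content is not stated, and they lack some of the peaks that pass the IDR threshold.

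The main set was the conservative thresholded list, which matches the ranked list made from the 2 true replicates. The background, called candidate peaks below, was the 89045 peaks of that ranked list that overlap neither the optimal nor the conservative list. Genes came from Ensembl release 115 (46890 genes on the 6 chromosomes, 19973 of them protein-coding) and sequence from WBcel235, the assembly that ce11 names. All peaks lay within its chromosome lengths. Coordinates are 1-based.

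A summit was called promoter-proximal when it lay within 500 bp of an annotated gene 5' end. Peaks were assigned to the gene with the nearest 5' end within 500 bp. Results without replicate 1 or without replicate 2 used the deposited thresholded list of the other replicate alone (272 and 209 peaks). These lists gave 159 and 124 genes with a peak, against 322 for the conservative list. A call lost there can therefore also reflect the shorter list. Shares were compared by two-sided Fisher's exact tests, 25 gene lists and 10 motifs each with Benjamini-Hochberg adjustment. Motifs and all 7-mers, both strands merged, were searched within 50 bp of the summit. The 7-mers were tested by one-sided Fisher's exact tests, adjusted over all 8192. Words found on chromosomes I, II and III were tested again on IV, V and X. Overlap of the replicates was set against 1000 random rotations of one list along each chromosome (one-sided). Motif presence and rank were compared by a two-sided permutation test with 100000 resamples. Intervals are Wilson intervals at 95% confidence. They cover the number of peaks only, since the depth of sequencing is unknown from these files. Peaks and genes are not biological replicates, so the tests describe these lists and not variation between animals.

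Before the data were examined, the groups, tests, gene lists, motifs and alternatives were fixed, as was the rule for the genes named. The rule takes the genes at the 20 conservative peaks of highest signal (the gene containing the summit, or the nearest gene, where no 5' end lies within 500 bp), hinf-1 in any case, and up to 4 members per list with a peak, by signal. The named motifs were all fixed motifs and the 5 7-mers with the smallest p. Genes named for other reasons are marked as chosen after their values were seen. A background without the peaks that pass IDR but are absent from the thresholded lists was added after seeing the data. The word and gene list tests were tested on simulated data. Of 50 words planted in 2% of windows 31 were recovered, and of 50 planted in 5% of windows 50 were recovered, with 0 calls among 8192 words when none was planted. Those windows were drawn at random from the candidates. The 0 calls therefore do not cover calls that arise from differences in GC content or from repeated gene copies. All 20 simulated lists of 40 genes with 8 hits were called, and 0 of 80 random lists. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.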

Results

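HINF-1 is the worm relative of human HINFP, a transcription factor of histone H4 genes. Its binding sites were mapped in young adults by ChIP-seq of the eGFP-tagged protein, with 2 biological replicates of 1 group. The conservative list held 567 peaks and the optimal list 630. The thresholded lists held 209 peaks for replicate 1 and 272 for replicate 2. Of the 567 conservative peaks, 470 (82.9%) overlapped the optimal list. The median conservative peak was 230 bp wide. The depth of sequencing is unknown from the peak lists.

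The first question was whether the replicates shared their peaks. Of the 209 peaks of replicate 1, 56.9% (95% Wilson interval 50.2 to 63.5) overlapped a peak of replicate 2. In replicate 2, 120 of 272 (44.1%, 38.3 to 50.1) overlapped replicate 1. Random rotations gave means of 0.27 and 0.279 shared peaks, and the permutation p was 0.001 in both directions, the smallest that 1000 rotations can give. The 20 conservative peaks of highest signal, which include those at his-67 and his-68, his-37, hil-4 and rpl-3, were all in both replicate lists. Among all 567 conservative peaks, 118 (20.8%) were in both lists and 289 (51%) in neither, so the weaker peaks rest on the joint ranking of the replicates.

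Histone genes were prominent among the strongest peaks. Of the 20 conservative peaks of highest signal, 11 were nearest to a histone gene, though ranks 1 and 2 were not. The peak between the divergent genes his-67 and his-68 (I:9988763-9989240, intergenic) had a signal value of 2984, rank 3. The peak 90 bp upstream of the H4 gene his-37 (V:9546887-9547138, intergenic) had 1740. The linker histone H1 gene hil-4 (V:4754135-4754412, 49 bp upstream) had 1252, the H3 and H4 pair his-59 and his-60 (IV:7487951-7488233, intergenic) 1173, and the pair his-63 and his-64 (IV:11406887-11407141) 1083. The median conservative peak had 64.7.

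**Figure D1:**
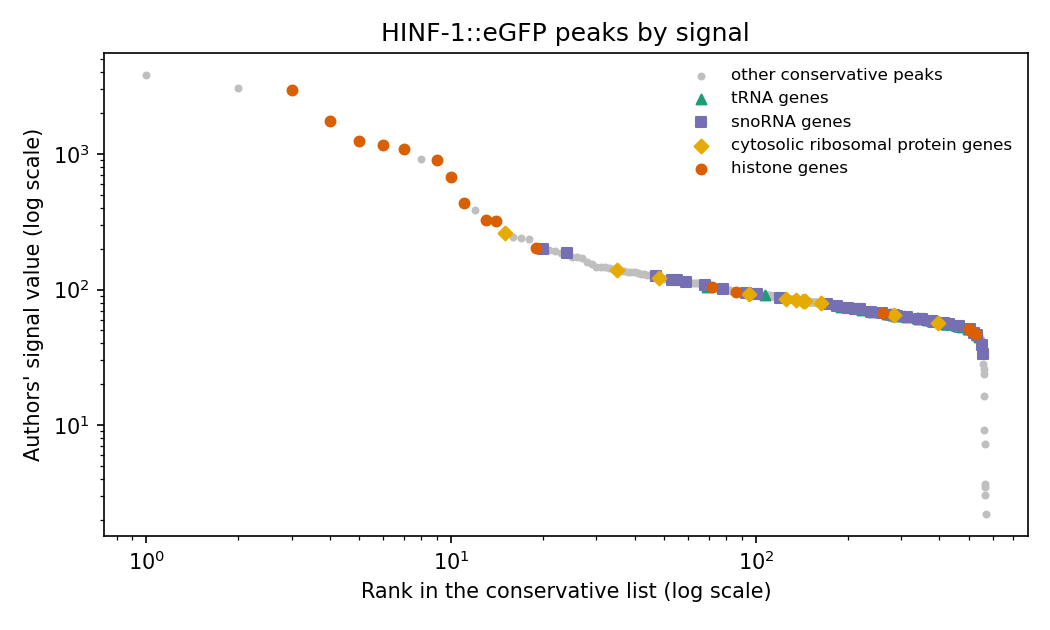
Authors' signal value of each of the 567 conservative peaks against its rank, both on log scales, with peaks at genes of 4 lists marked. Of the 17 peaks at histone genes, 11 are among the 20 of highest signal, while the tRNA and snoRNA peaks have medians of 59.4 and 67.7.

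Other histone genes followed. The H1 gene his-24 (X:14489929-14490173) had a signal value of 900.9, hil-5 (I:5774425-5774691) 679.2, the pair his-61 and his-62 (IV:7486223-7486523) 438.2, hil-3 (X:8159020-8159194) 324.6, the pair his-5 and his-6 (V:8535050-8535200) 320.1 and hil-2 (IV:6294143-6294258) 201.7. By list, 16 of the 40 histone genes that could be assigned a peak had one, with an odds ratio of 43.6 (Fisher's exact, adjusted p = 5.88e-18). For histone H4 genes the count was 6 of 9, with an odds ratio of 127 (Fisher's exact, adjusted p = 6.03e-09). These genes are also in the histone list, and no test compared them with the other histone genes. The odds ratio of the histone list was 89.9 without replicate 1 and 98.2 without replicate 2, and that of histone H4 genes was 163.3 and 282. Counting every summit within 500 bp, so that a peak between divergent genes serves both, 24 of the 81 annotated histone genes had a peak. They included 5 of 9 H1 genes and 6 of 16 H4 genes. The other 57 annotated genes had none. Among genes with any peak of the ranked list within 500 bp, 5 of 7 H1, 6 of 11 H4 and 13 of 34 other histone genes had a conservative peak.

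**Figure D2:**
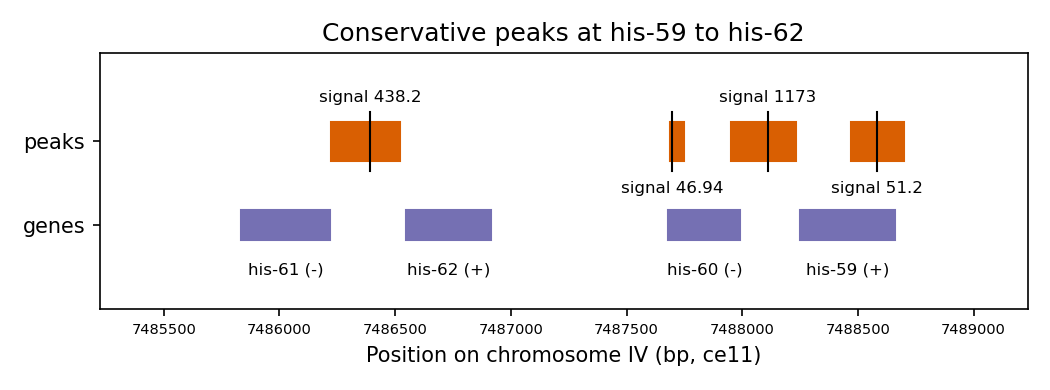
Conservative peaks (bars with the summit as a line, signal value beside it) and the histone genes his-59 to his-62 with their strands, by position on chromosome IV. The peaks of 1173 and 438.2 lie between genes transcribed away from each other, and 2 weaker peaks of 51.2 and 46.9 lie at his-59 and his-60.

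The remaining peaks among the 20 strongest were not at histone genes. The strongest of all (V:10341828-10342284, intergenic) had a signal value of 3826 and lay 46 bp upstream of K07C5.13. The next (II:13016455-13016748) had 3045 and lay in an intron of max-2. A peak in an intron of lin-9 (III:8901160-8901410) had 925.2, one in an intron of Y71A12B.10 (I:13958499-13958664) 387, one in an intron of srh-303 (V:17832366-17832471) 241.9 and one in an intron of cmk-1 (IV:1831314-1831543) 235.8. An intergenic peak near the piRNA gene 21ur-15381 (IV:15896005-15896088) had 240.1. The ribosomal protein gene rpl-3 (III:3867511-3867642, 269 bp upstream) had 263.3 and the snoRNA gene ZK994.7 (V:8500515-8500594, within an intron of pxn-1) had 200.6. Some of these peaks lie in repeated sequence, with a share of genome-unique 31-mers of 0.525 at K07C5.13, 0.235 in max-2 and 0 near 21ur-15381.

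At hinf-1 itself (I:14791040-14794392), no peak of the conservative, optimal or replicate thresholded lists had a summit within 500 bp of the 5' end or inside the gene. The nearest conservative summit was 30202 bp away. The ranked list of the replicates had a peak 100 bp from the 5' end at rank 9024 of 89784, with a signal value of 30.96.

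Cytosolic ribosomal protein genes and 4 lists of small noncoding RNA genes were also overrepresented. Among cytosolic ribosomal protein genes, 10 of 64 had a peak, with rpl-3 at 263.3, rpl-35 at 139.7, rpl-15 at 122.5 and rpl-41.2 at 93.1 in signal value (odds ratio 11.9, Fisher's exact, adjusted p = 2.16e-07). Of snoRNA genes, which guide RNA modification, 38 of 258 had a peak, led by ZK994.7 at 200.6, C51F7.4 at 184.4, F59C6.15 at 125.8 and Y75B12B.12 at 118 (odds ratio 12.1, Fisher's exact, adjusted p = 2.25e-24). Of tRNA genes 31 of 390 had a peak, with a highest signal value of 105 (odds ratio 5.84, Fisher's exact, adjusted p = 1.38e-12). Of the spliced leader RNA genes 7 of 16 had one, with sls-2.1 at 99.6, sls-2.8 at 75.95, sls-2.4 at 73.8 and sls-2.5 at 70.2 (odds ratio 49.5, Fisher's exact, adjusted p = 9.78e-09). Of snRNA genes 13 of 80 had one, of which 7 were the same spliced leader genes (odds ratio 12.5, Fisher's exact, adjusted p = 2.31e-09). Without replicate 2, the tRNA and spliced leader calls ended, at odds ratios of 2.25 and 13.6 (Fisher's exact, adjusted p = 0.2 for each), and snRNA genes had an odds ratio of 6.91 (Fisher's exact, adjusted p = 0.0457). Without replicate 1, ribosomal protein genes had 19.3.

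Smaller groups passed the test with few members. They were 4 of 25 respiratory chain genes (cyc-2.1 88.8, cox-5A 87.4, atp-1 56.3, cox-5B 55.2 in signal value), 3 of 26 translation factors (eif-3.C 158.2, eef-2 60.2, eef-1G 57.8), 3 of 30 chromatin regulators (lin-9 111.2, set-2 86.55, lin-52 67) and 3 of 33 heat shock genes (dnj-9 79.4, hsp-3 59.7, hsp-1 56.5). Their Fisher's exact adjusted p were 0.00166, 0.0195, 0.0264 and 0.0314. Pseudogenes had fewer peaks, 3 of 1157 (odds ratio 0.154, Fisher's exact, adjusted p = 4.78e-05). The translation factor, chromatin and heat shock calls ended without either replicate, the respiratory chain call without replicate 1 and the pseudogene call without replicate 2. The other 13 lists did not pass. No gene of the aminoacyl-tRNA synthetase, sperm MSP, intestine, muscle, neuron or rRNA lists had a peak. Each of the DNA repair, proteasome, splicing, mitochondrial ribosomal protein, germline and collagen lists had 1 gene (exo-3, pas-1, prp-39, mrpl-50, pgl-3 and col-42), and the DNA replication and cell cycle list had 2, cdc-48.1 and pcn-1.

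Against the 2000 candidate peaks next in signal, only the histone, histone H4 and snoRNA lists passed, with odds ratios of 9.41, 29.8 (with 0.5 added to each cell) and 2.80. These 2000 were the candidates of highest signal. Some of them passed IDR but were absent from the thresholded lists, so not all were weaker than the conservative peaks. The tRNA list fell to an odds ratio of 1.10 (Fisher's exact, adjusted p = 1), and the calls for the ribosomal protein, spliced leader, snRNA, respiratory chain, translation factor, heat shock and pseudogene lists ended there too. The chromatin list also missed the threshold, with a higher odds ratio of 15.9 (0.5 added to each cell) on 3 of 3 genes (Fisher's exact, adjusted p = 0.103).

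**Figure D3:**
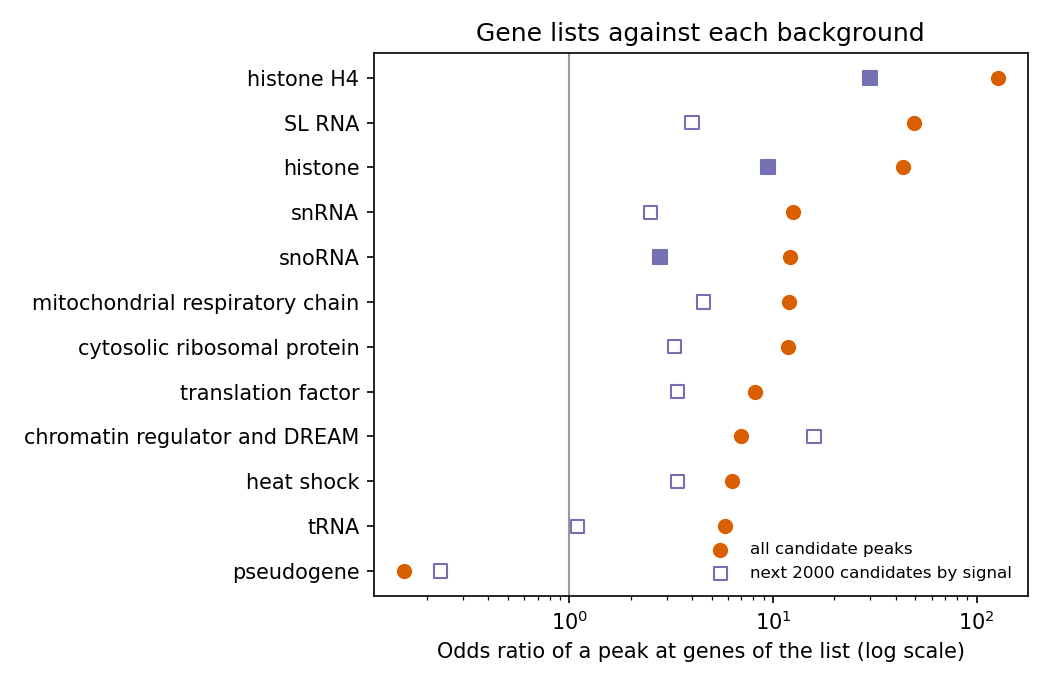
Odds ratio, on a log scale, of a peak at the genes of each list that passed the test, against all candidate peaks (circles) and against the 2000 next in signal (squares, filled where the adjusted p is under 0.05). Histone H4 genes had 127 and tRNA genes 5.84 against all candidates, and tRNA genes 1.10 against the next in signal.

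Binding was promoter-proximal more often than in the candidate peaks. Of the 567 conservative summits, 328 (57.8%, 95% Wilson interval 53.7 to 61.8) lay within 500 bp of a gene 5' end, against 29.5% of candidates (odds ratio 3.27, Fisher's exact, p = 4.54e-44). Of those 328, 198 (60.4%) lay upstream of the 5' end. These counts use 5' ends of all annotated genes, noncoding ones included. With protein-coding genes only, the shares were 39.9% of conservative and 19.7% of candidate summits (odds ratio 2.71). Of the 2000 candidates next in signal, 36.8% lay within 500 bp of any gene 5' end (odds ratio 2.36). Intergenic summits made up 45.9% of conservative and 28.0% of candidate peaks, introns 13.6% and 29.7%, coding exons 17.3% and 33.1%, noncoding exons 13.6% and 4.07%, 5' UTRs 4.06% and 2.15%, and 3' UTRs 5.64% and 2.99%.

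The X chromosome held fewer peaks than the candidates did. There were 54 peaks on X (9.52%, 95% Wilson interval 7.37 to 12.2), among them those at his-24 and hil-3, against 17.9% of candidates (odds ratio 0.483, Fisher's exact, p = 3.10e-08, or 1.86e-07 adjusted over the 6 chromosomes). Of the 129 peaks that passed IDR but were absent from the conservative list, 25 were on X. That is a higher share than among the conservative peaks, so the lower share on X partly reflects their absence. The other chromosomes were tested in addition to the planned test of X. Chromosomes I (19.6% against 15.6%), III (18.2% against 14.4%) and IV (20.6% against 15.2%) held more peaks than the candidates did (Fisher's exact, adjusted p = 0.021, 0.021 and 0.00198), while II and V did not pass (Fisher's exact, adjusted p = 0.0613 and 0.349).

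The sequence around summits was examined for CGTCCG, taken as the core of the site of the human relative. It occurred at 13 of 567 summits (2.29%, 95% Wilson interval 1.34 to 3.88) and at 1.48% of candidates, a difference that did not pass (Fisher's exact, adjusted p = 0.144). The longer core ACGTCCG occurred at 0.529% and 0.321% (Fisher's exact, adjusted p = 0.436), and CACGTG at 3.00% and 2.2% (Fisher's exact, adjusted p = 0.216). The E2F-like TTTSGCGC was more frequent, at 2.82% against 0.794% (Fisher's exact, adjusted p = 0.000131). GAGAGA was at 10.1% against 6.50%, CCGCCC at 4.59% against 2.42% and CG at 97.5% against 94.8% (Fisher's exact, adjusted p = 0.00297, 0.00332 and 0.00332). The AT-rich TTTTTTTT (3.88% against 7.84%), TGATAA (3.88% against 7.84%) and TTTCAG (11.3% against 17.8%) were less frequent (Fisher's exact, adjusted p = 0.000514, 0.000514 and 0.000131). The conservative windows had a median GC content of 45.5% and the candidates 39.6%. With candidates matched on GC, TTTSGCGC alone of these 7 passed. Against the 2000 candidates next in signal it did not (2.82% against 1.2%, Fisher's exact, adjusted p = 0.0549), and of the 7 CG alone passed there. No motif was associated with signal rank after adjustment over the motifs, the smallest adjusted permutation p being 0.057 for TTTCAG.

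Among all 7-mers, 302 of 8192 were more frequent at conservative summits. The 5 with the smallest p were CGAACCC at 5.11% of summits and 0.532% of candidates, CGCGCGC at 5.11% and 0.555%, GGTTCGA at 5.64% and 0.982%, AGCGCGC at 3.88% and 0.422%, and CTCTACC at 4.59% and 0.696%. Of the 29 peaks with CGAACCC, 13 lay within 500 bp of a tRNA gene, as did 17 of the 32 with GGTTCGA and none of the 29 with CGCGCGC. Of 110 words found on chromosomes I, II and III, 67 (60.9%) passed on IV, V and X, while 7.15% of the other words had an unadjusted Fisher's exact p under 0.05 there. Without replicate 1 or 2, GGTTCGA was at 2.21% and 2.39% of summits and no longer passed (Fisher's exact, adjusted p = 0.595 and 0.778). CGAACCC was at 2.57% without replicate 1 (Fisher's exact, adjusted p = 0.0433) and at 2.87% without replicate 2, where it did not pass (Fisher's exact, adjusted p = 0.0683). The count of words fell to 124 with GC-matched candidates and to 35 against the 2000 candidates next in signal. Copies of tRNA and histone genes share sequence, so these windows are not independent.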

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

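The tests of GGGACACA at absent, tRNA and snoRNA peaks were chosen in their present form after results had been seen. The odds ratios against the next candidates were planned as alternatives and were used to weigh an explanation only after they had been seen. In the ranked list behind the conservative set, 129 peaks passed the IDR threshold and were absent from the deposited thresholded list, 18.5% of the 696 that passed, and they entered the comparisons of the report only as part of the candidate background. The strongest (X:15810958-15811184) had a signal value of 2701. Repeated sequence fits these sites: the median share of genome-unique 31-mers was 0.1 in the absent peaks and 1 in the conservative ones, a difference of 0.9 (permutation p = 1e-05, the smallest the resamples can give). GGGACACA, a word found in the strongest conservative peaks, occurred at 0% of the absent peaks. It occurred at 4 of 520 conservative peaks within their signal range and outside the 20 strongest, in which it was picked (Fisher's exact p = 1). Without those 20, the 520 reached a signal value of only 194.8 (median 64.9), against 2701 in the absent peaks (median 116.7). The sets are thus not matched in signal, and too few peaks carry the word to test the same sequence-specific binding. What the authors' filter removed is not stated, and no biological explanation was tested.

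Of the 81 histone genes, 57 had no conservative peak, among them all those of the repeated core cluster on II and the repeated his-49 to his-52 copies on V. Repeated sequence may explain much of this: the median share of unique 31-mers within 250 bp of the 5' end was 0.796 in genes with a peak and 0 in those without, a difference of 0.796 (permutation p = 0.00109). Repeated copies in clusters were shuffled as separate genes, so this p may be too small. Genes in repeated sequence could still have a peak, as his-17, his-18 and copies of his-45 and his-47 did with shares of 0.0361, 0.0488, 0.0658 and 0 (these and the genes on II and V were named after their values were seen). Repeated sequence cannot explain the 10 genes without a peak that lie in unique sequence, with a share of 0.9 or more. These were hil-1, hil-7, hil-8, his-35, his-41, his-69, his-70, his-71, his-72 and his-74, listed after their values were seen. Of them, his-35 and his-41 share a peak of the optimal list with a signal value of 50.8.

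Peaks at tRNA and snoRNA genes carried GGGACACA at 0% of 68 peaks outside the 20 strongest, and the other peaks outside the 20 strongest at 4 of 479 (Fisher's exact p = 1). The 20 strongest were left out because the word was picked in them, and so few peaks with the word remain that the same sequence-specific binding stays open. For tRNA genes, signal that strong peaks share whether or not they pass IDR may account for the enrichment, since the odds ratio against the next 2000 candidates was 1.10 (Fisher's exact, adjusted p = 1). For snoRNA genes that ratio was 2.80 (Fisher's exact, adjusted p = 0.000577), which is not the result predicted for such a signal. The next candidates were not matched to the conservative peaks in signal, however. A shared signal that is stronger at snoRNA genes could also give this ratio, so the explanation stays open. Immunoprecipitation background at highly transcribed genes was not tested, and the control was not used here.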

How the results depend on the processing

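No paired analysis was possible because there is 1 group. Of 467 alternative values, 410 kept their direction and side of the threshold or stayed within 1.5 times the count. Among these were all alternatives for replicate overlap (41.2% to 74.6%), promoter share (39.9% to 70.4%) and X share (5.99% to 9.52%), and those for the histone, histone H4 and snoRNA lists. The 410 also include every alternative of the gene lists that did not pass in the main test and so had no call to lose. Chromosome-matched random positions cannot give an X share. The background chosen after seeing the data changed no call. It kept 88904 of the 89045 candidates, so it could hardly have changed one.

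The number of overrepresented lists was 11. It was 6 to 7 with 1 replicate left out and 3 against the 2000 candidates next in signal, where fewer genes are tested and the odds ratios of the enriched lists fell, except that of the chromatin list. That last background gave odds ratios of 3.28 for ribosomal protein, 3.40 for translation factor, 15.9 for chromatin, 4.54 for respiratory chain, 3.40 for heat shock, 4 for spliced leader, 1.10 for tRNA, 2.50 for snRNA and 0.234 for pseudogene lists, none past the threshold. Translation factors also missed it with the optimal set (4.67), the 284 peaks of highest signal (4.65) and 200 bp (6.73), heat shock genes with those 284 peaks (3.49) and 200 bp (4.30), and chromatin regulators with 200 bp (9.79). With 1 replicate left out, odds ratios ranged from 0 to 5.30 for translation factors (0 of 25 genes without replicate 2, a reversed direction), 5.84 to 9.48 for chromatin, 5.53 to 15 for respiratory chain, 5.11 to 8.25 for heat shock, 13.6 to 47.2 for spliced leader, 6.91 to 13.4 for snRNA, 15.1 to 19.3 for ribosomal protein, 89.9 to 98.2 for histone, 163.3 to 282 for histone H4, 2.25 to 3.61 for tRNA and 0 to 0.27 for pseudogene lists. Translation factor, chromatin and heat shock lists missed the threshold without either replicate, respiratory chain without replicate 1, and spliced leader, tRNA and pseudogene lists without replicate 2.

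The 302 words became 117 to 171 with 1 replicate left out, 609 with random positions, 35 against the candidates next in signal and 124 with GC-matched candidates. CGTCCG passed against random positions only (2.29% against 1.01%), as did CACGTG (3.00% against 1.71%). GAGAGA and CCGCCC lost their calls within 25 bp. Against the candidates next in signal, TTTTTTTT (3.88%) and TTTCAG (11.3%) were no longer less frequent, and GAGAGA, CCGCCC, TGATAA and TTTSGCGC also lost their calls. Those of CCGCCC and TGATAA ended without replicate 2, and that of CG without either replicate. CG within 100 bp (98.9%) was no longer more frequent. The cause was not tested for any of these changes. The unknown depth limits what the absence of a peak shows.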

Other observations

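The tests of GGGACACA in this part were chosen after the result was seen, and the 8-mer test was planned. The strongest peaks shared a sequence word. GGGACACA lay within 50 bp of the summit in 13 of the 20 peaks of highest signal, 9 of the 11 near a histone gene and 4 of the other 9, and in 17 of all 567 conservative peaks. Those 4, at K07C5.13 and in introns of max-2, Y71A12B.10 and srh-303, were copies of 2 sequences when peaks that share a 31-mer are merged. The word was at 0.155% of candidate summits, and the genome holds 1353 sites of it. Among the 20 strongest, the histone peaks with the word were those at his-67 and his-68, his-37, hil-4, his-59 and his-60, his-24, hil-5, hil-3, his-5 and his-6, and hil-2. Of those 20, the histone peaks at his-63 and his-64 and at his-61 and his-62 lacked it. Counting all conservative peaks within 2000 bp of a histone gene, 12 of 29 had the word.

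A candidate explanation is that the word is part of the sequence bound by HINF-1, set against a word that histone promoters share for another reason. The word was picked in the 20 strongest peaks, so these can test neither. Outside them and farther than 2000 bp from any histone gene, with peaks that share a 31-mer counted once, 1 of 476 carried it (0.21%) against 0.162% of candidates (Fisher's exact p = 0.539). Outside the 20 strongest, 4 peaks carried the word, and all but this 1 lay within 2000 bp of a histone gene. Either explanation allows the word near histone genes. With 1 peak farther away, the explanations cannot be told apart. Most GGGACACA sites in the genome had no conservative peak, so the word by itself does not predict a peak of this list. With the depth unknown, the lack of a peak does not show a lack of binding.

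Other words were also more frequent at conservative summits. ATGTGTCC, at 19 summits, and CCCCGCAG, at 14, had smaller p (Fisher's exact, adjusted p = 1.28e-13 for each) than GGGACACA (Fisher's exact, adjusted p = 2.36e-12). Both can overlap TGTGTCCC, the reverse complement of GGGACACA, so the word may be part of a longer sequence. No longer sequence was tested, and the tests of GGGACACA used exact matches only. The 8-mer TTCTAGAA lay at 26 summits (4.59% against 0.617% of candidates, Fisher's exact, adjusted p = 8.01e-11), and GGGTTCGA, a sequence like the internal promoter box of tRNA genes, at 24 (4.23% against 0.293%, Fisher's exact, adjusted p = 3.65e-15).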
